A study of Homo sapiens with 16 samples.

How the data were processed

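Per the labels, HCC4006 cells were plated, grown for 24 hours, treated for 24 hours with DMSO, gefitinib, AZ1366 or both (100 nM each), trypsinized and frozen. Total RNA was extracted with a miRNeasy kit and libraries of polyA RNA were made with the TruSeq version 2 kit; whether they keep the strand is not stated. The deposited values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library) for each of 24293 loci in 16 libraries. Per the submitters' processing notes TopHat 1.4.1, Cufflinks 1.3.0 and Cuffdiff were used with the hg19 genome, and the notes do not say what each did, which annotation was used or whether libraries were scaled further. Values were used as the authors deposited them; no library was left out and no per-sample column went unused. Read counts were not analysed here, so the depth per library is unknown: at low abundance the values showed no steps of whole reads (for loci with a mean of at most 0.05 FPKM, the fullest bin of width 0.05 held at most 3.65% of the ratios). There were 0 pairs of identical libraries.

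Loci were tested when their mean over the 16 libraries was at least 1 FPKM, which kept 11647; 19605 loci were above 0 in at least 1 library and 4688 were at 0 in all of them. Names were taken from the file, and 643 loci without a symbol and 27 whose symbol had become a date were matched by RefSeq transcript, which named 563 and 26 of them. Of the tested loci, 315 carry the joined symbols of more than 1 gene and 203 share a symbol with another locus, so values of the latter, such as PSMB9 and HLA-DMA, may cover part of a gene's reads. Coordinates are the locus intervals of the file on hg19. Transcript length and GC content came from a later annotation (GENCODE, GRCh38) by gene name, for 11311 tested loci (97.1%).

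The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a factor of 4 treatment groups, moderated variances with a mean-variance trend and 12 residual degrees of freedom; p-values were two-sided and adjusted by Benjamini-Hochberg over the tested loci, with a threshold of 0.05 and no minimum fold. The 7 comparisons were gefitinib, AZ1366 and the combination against vehicle, the combination against each single compound, the interaction, and the AZ1366 effect averaged over gefitinib. Fold changes carry the standard error of the model, and group levels the mean and SD of 4 libraries. AXIN2 and NKD1 fell below the filter and were compared by an exact permutation test of group means, two-sided. The 36 gene lists, of 775 genes, were drawn from general knowledge before the data were examined, and 33 had at least 5 tested members. Lists were tested against the other loci with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Member counts are given over all tested loci and adjusted over the list alone. Agreement of effects was measured across loci by Pearson and Spearman correlation with a jackknife over libraries, between contrasts that share no library for each compound with and without the other, and for the main effects of the 2 compounds over all 16 libraries and over 1296 splits that measure them in separate libraries.

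Genes were named by a rule fixed before the data were examined: in each comparison the 6 largest rises and 6 largest falls among called loci whose groups did not overlap (no such condition for the interaction and the averaged effect), up to 4 members with the smallest p in each called list, and 10 fixed genes (AXIN2, NKD1, TNKS, TNKS2, EGFR, DUSP6, CCND1, MYC, MKI67 and BCL2L11). The text prints part of the genes that the rule gave, picked after their values were seen, and some genes that it gave are not reported here. CTGF and ANKRD1, as YAP targets outside the rule in some comparisons, DKK1 outside the combination against gefitinib, and the genes of the observations on further gene groups were chosen after their values were seen.

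Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter and a minimum mean of 5 FPKM (8037 loci), quantile normalization, median-ratio scaling, no mean-variance trend, only the libraries compared, the replicate number as a block, a minimum absolute log2 change of 1, and leaving out each library in turn. A correction of each library for a smooth trend (5 spline terms each) on transcript length and GC content, and leaving out CTRL 1 and AZ1366 1 together, were added after seeing the data. The method was tested on simulated data with these libraries' spread and 200 changed loci of 11647. For gefitinib against vehicle it recovered 44% of log2 changes of 0.25, 94% of 0.5 and 100% of 1, with 9 false calls (5.06%); for the interaction 8%, 72% and 100%, with 6 false calls (4.11%). Of 40 simulated lists of uncorrelated genes camera called all 10 shifted and 1 other.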

Results

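Transcript abundance was measured by sequencing polyA RNA of HCC4006, an established non-small cell lung cancer line that carries an activating EGFR mutation. Cells had been treated for 24 hours with DMSO (vehicle), with gefitinib, an inhibitor of the EGFR kinase, with AZ1366, a tankyrase inhibitor, or with both compounds, each at 100 nM. Each of the 4 groups held 4 libraries, 16 in all. The deposited FPKM of a library summed to between 433357 and 478179 over 24293 loci, and between 11326 and 11799 loci reached 1 FPKM. The number of reads behind these values is not given, so the depth is unknown and no counting interval can be stated. The 100 most abundant loci took 27.3 ± 0.747% of the summed FPKM with vehicle, 29.5 ± 1.11% with gefitinib, 30.4 ± 1.4% with AZ1366 and 32.9 ± 0.890% with both (SD, n = 4 per group). Correlations of log2 values across loci ran from 0.991 to 0.998 for the 24 pairs of libraries within a group and from 0.923 to 0.992 for the 96 pairs between groups. The first principal component held 71.8% of the variance and the second 16.6%. Vehicle libraries scored between -39.3 and -34.0 on the first component, gefitinib libraries between 5.32 and 13.3, and combination libraries between 31.0 and 38.1. AZ1366 replicate 1 scored -19.6, nearer to vehicle than the other 3 AZ1366 libraries at -6.50 to -3.10. The labels do not say whether the 4 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, part or all of which may be technical.

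**Figure D1:**
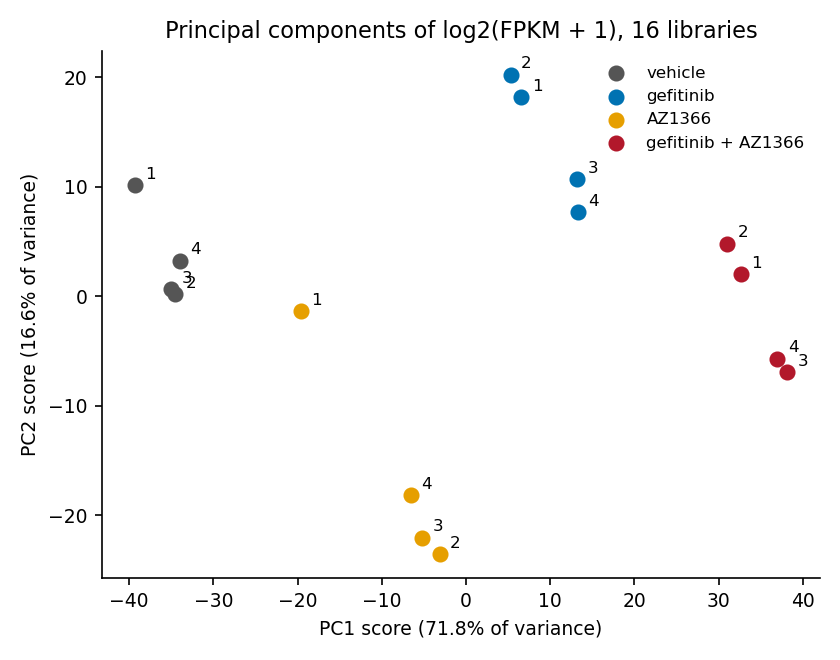
Scores of the 16 libraries on the first and second principal components of log2(FPKM + 1), coloured by treatment and numbered by replicate. The first axis (71.8% of the variance) runs from vehicle to the combination, and AZ1366 replicate 1 lies at -19.6, apart from the other AZ1366 libraries.

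The comparison of gefitinib with vehicle asks how these cells respond to EGFR kinase inhibition. Changes are in log2(FPKM + 1), which shrinks those at low FPKM. VTCN1, encoding an inhibitory T cell ligand, rose most, by 3.18 ± 0.060 (SE, adjusted p = 1.13e-16), from 3.82 ± 0.146 to 42.9 ± 3.08 FPKM (SD, n = 4, hg19 chromosome 1, 117686209 to 117753582). The chemokines CXCL11 (2.92 ± 0.089) and CCL2 (2.42 ± 0.058; chromosome 17, 32582296 to 32584220) rose with it, as did the metalloproteinase gene MMP7 (2.71 ± 0.078; chromosome 11, 102391239 to 102401478), the trypsin inhibitor gene SPINK1 (2.29 ± 0.079) and TNFSF10, which encodes the death ligand TRAIL (2.27 ± 0.10). The largest fall was that of DUSP6, which encodes an ERK phosphatase and is transcribed in response to ERK activity: it went from 23.5 ± 0.334 to 2.71 ± 0.235 FPKM (chromosome 12, 89741837 to 89746296), a log2 change of -2.73 ± 0.080 with adjusted p = 3.03e-14. PHLDA1 (-2.54 ± 0.093; chromosome 12, 76419227 to 76425556), NT5E (-2.21 ± 0.11), G0S2 (-2.16 ± 0.089), the FOS family gene FOSL1 (-2.03 ± 0.10) and the ETS factor gene ETV1 (-1.97 ± 0.062; chromosome 7, 13930856 to 14031050) followed.

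Genes driven by ERK signalling fell as a group: 23 of 26 tested members fell and none rose, with a median log2 change of -1.20. For ERK output, camera gave adjusted p = 2.08e-11, and 0.248 with an estimated correlation. Cyclin D1, CCND1, fell by 1.59 on the log2 scale, from 197 ± 8.87 to 64.9 ± 4.77 FPKM (chromosome 11, 69455873 to 69469242), and MYC fell by 0.82 from 5.73 ± 0.762 to 2.79 ± 0.0824 FPKM (chromosome 8, 128748315 to 128753680). The polyamine synthesis gene ODC1 changed by -1.44 ± 0.061. Every one of the 36 tested genes of G1/S and DNA replication fell (median -0.56), among them the origin licensing gene CDC6 (-1.01 ± 0.070) and the replication factors ORC1 (-0.90 ± 0.055) and MCM10 (-1.15 ± 0.079). G1/S genes had camera adjusted p = 4.68e-11, and 0.248 with an estimated correlation. Of the G2/M and mitosis genes 35 of 36 fell (median -0.63), including the mitotic kinase PLK1 (-0.98 ± 0.065), and MKI67, the proliferation marker, went from 26.3 ± 1.83 to 11 ± 2.27 FPKM. For G2/M genes, camera gave adjusted p = 1.44e-09, and 0.249 with an estimated correlation. Ribosome biogenesis genes fell in 22 of 23 cases (median -0.89), with DKC1 at -1.0 ± 0.063 and the RNA polymerase I subunit gene POLR1B at -0.89 ± 0.057. Ribosome biogenesis had camera adjusted p = 4.85e-10, and 0.248 with an estimated correlation. The counts adjusted over the list alone were the same in these 4 lists.

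Interferon-stimulated genes rose together, 28 of 29 of them, with a median of 1.02. For interferon-stimulated genes, camera gave adjusted p = 1.44e-14, and 0.248 with an estimated correlation. IFI27 went from 10.7 ± 2.56 to 47.6 ± 3.14 FPKM, RSAD2 changed by 1.74 ± 0.11, and OASL by 0.89 ± 0.055. Antigen presentation genes followed, with 15 rises and 1 fall among 17, a median of 0.59 and camera adjusted p = 3.31e-06 (adjusted p = 0.248 with an estimated correlation). The immunoproteasome gene PSMB9 changed by 1.42 ± 0.083 and the class II chaperone gene HLA-DMA by 1.21 ± 0.080, both at loci that the file lists more than once for alternative versions of the region. NF-kB and inflammatory genes gave 8 rises and 4 falls among 14 (median 0.43), with LTB up by 2.65 ± 0.10, ICAM1 up by 1.26 ± 0.10 and CD274 at -1.31 ± 0.058. NF-kB genes had camera adjusted p = 0.0417, but 0.663 with an estimated correlation and 0.0519 without GEF 1. Adjusted over the list alone, the counts of these 3 lists did not change.

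Genes that promote apoptosis or mark FOXO activity were on balance higher. BMF, a pro-apoptotic BCL2 family member, rose from 6.04 ± 0.451 to 25.2 ± 1.53 FPKM (chromosome 15, 40380092 to 40401075; log2 1.90 ± 0.072, adjusted p = 6.05e-13), BBC3 rose by 1.06 ± 0.10, BIK by 0.70 ± 0.082 and BCL2L11, which encodes BIM, by 0.41 ± 0.062 (adjusted p = 2.25e-05; chromosome 2, 111878491 to 111926022). The list's counts were 5 rises and 2 falls among 10 (median 0.20). For pro-apoptotic genes, camera gave adjusted p = 0.0417, but 0.452 with an estimated correlation, 0.134 after length and GC correction and 0.0637 without GEF 4. FOXO and PI3K feedback targets gave 11 rises and 7 falls among 22 (median 0.16), with FBXO32 at 1.63 ± 0.063, PIK3IP1 at 1.54 ± 0.10 and YPEL3 at 1.35 ± 0.056. FOXO targets had camera adjusted p = 0.0417, but 0.702 with an estimated correlation and 0.0586 after quantile normalization. Kinase inhibitors of the cell cycle and p53 targets gave 11 rises and 3 falls among 21 (median 0.22), with TP53INP1 at 1.83 ± 0.094 and PLK3 at -0.59 ± 0.062. For cell cycle inhibitors and p53 targets, camera gave adjusted p = 0.0144, and 0.622 with an estimated correlation. Lysosome and autophagy genes gave 13 rises and 2 falls among 25 (median 0.24, camera adjusted p = 0.000727) and NRF2 targets 12 rises and 2 falls among 18 (median 0.29, camera adjusted p = 0.00611), each with adjusted p = 0.377 with an estimated correlation; the autophagy gene GABARAPL1 changed by 1.7 ± 0.053 and the ferritin gene FTH1 by 0.97 ± 0.076. Adjusted over the list alone, NRF2 targets gave 12 rises and 3 falls and the other 4 lists the same counts.

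Glycolysis, lipid synthesis and heat shock genes were lower on balance. Glycolysis genes fell in 18 of 21 cases (median -0.31), with HK2 at -1.19 ± 0.079 and ENO2 at -0.78 ± 0.063. Glycolysis had camera adjusted p = 0.000226, and 0.377 with an estimated correlation. Fatty acid synthesis genes fell in 10 of 13 cases and 1 rose (median -0.51), led by FASN at -1.10 ± 0.12. For fatty acid synthesis, camera gave adjusted p = 0.0144, and 0.663 with an estimated correlation. Cholesterol synthesis genes fell in 15 of 24 cases and 1 rose (median -0.24), which was TM7SF2 at 1.29 ± 0.073. Cholesterol synthesis had camera adjusted p = 0.0417, but 0.663 with an estimated correlation, 0.0512 after quantile normalization, 0.0552 without GEF 1 and 0.0597 without GEF 2. Heat shock genes fell in 9 of 15 cases and 1 rose (median -0.38), with STIP1 at -0.62 ± 0.057 and HSPB1 at 1.03 ± 0.059. For heat shock genes, camera gave adjusted p = 0.0417, and 0.622 with an estimated correlation. Adjusted over the list alone, 1 glycolysis gene rose as well, and the other 3 lists kept their counts. EGFR itself went from 77.7 ± 4.39 to 38.1 ± 4.06 FPKM (log2 -1.01 ± 0.11; chromosome 7, 55086725 to 55275031).

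Of 11647 loci 7521 passed an adjusted p of 0.05 (limma), 3226 higher and 4295 lower. Of them 382 changed by at least 1 in log2, 258 up and 124 down. The change went with transcript length (Spearman rho -0.211). Camera called 16 of 33 lists, and 0 with an estimated correlation (6 at an unadjusted p under 0.05). Fry, which does not compare with other genes, called 24.

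**Figure D2:**
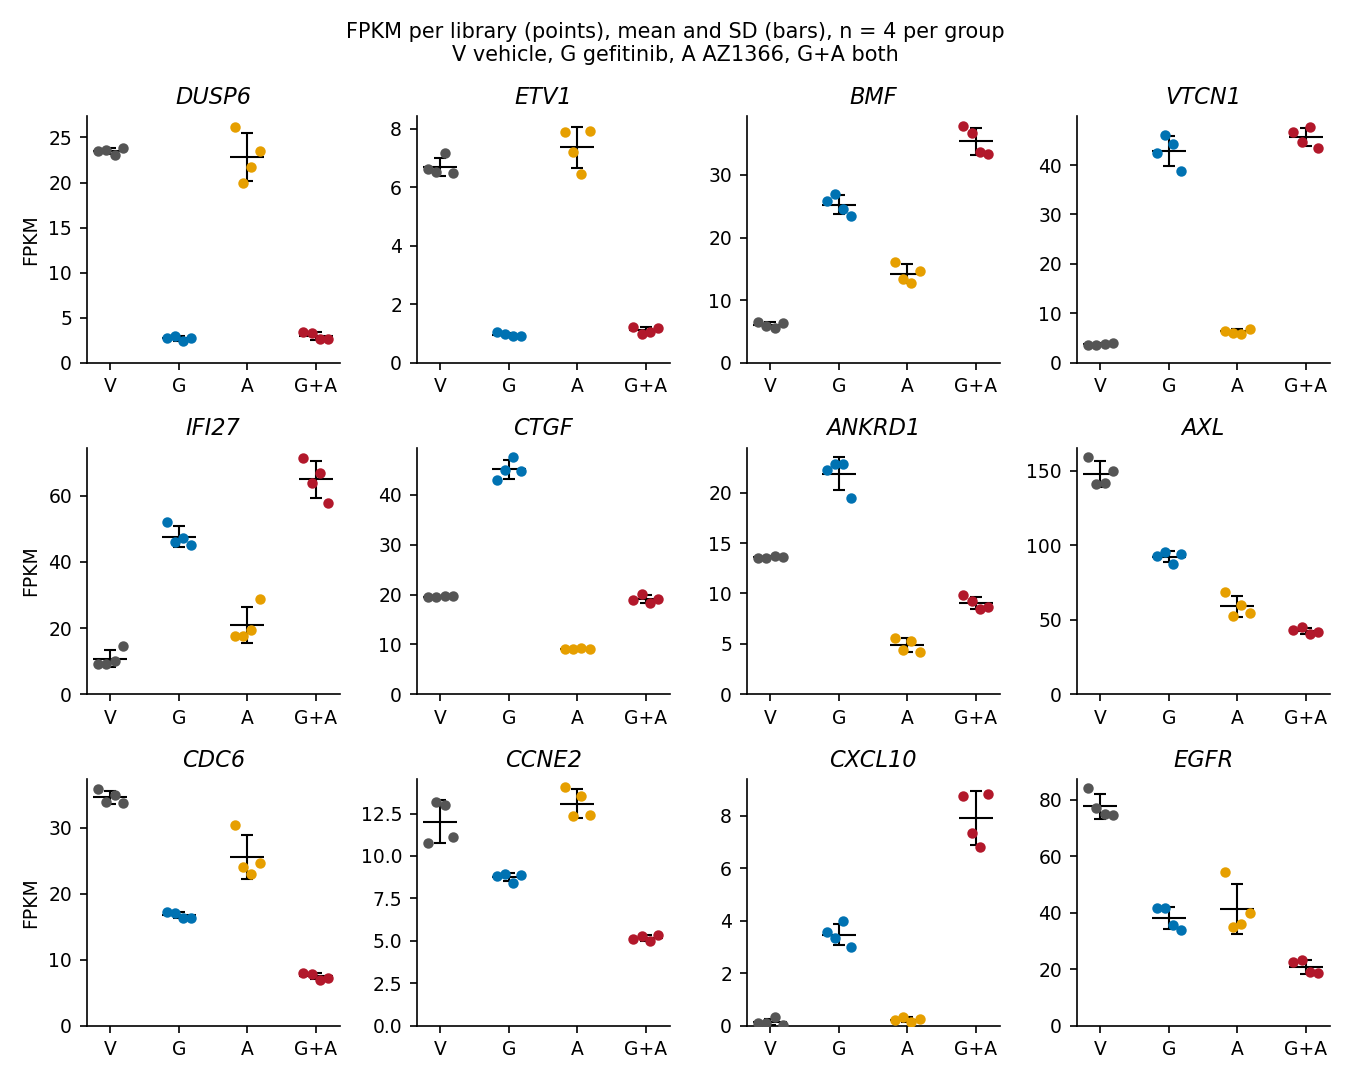
FPKM of 12 genes in each library (points) with the group mean and SD (bars; n = 4), for vehicle (V), gefitinib (G), AZ1366 (A) and both (G+A), each vertical axis starting at 0. DUSP6 and ETV1 were low in both groups with gefitinib, CTGF and ANKRD1 were lower with AZ1366 than without it at the same gefitinib treatment, and CDC6 and CCNE2 were lowest with both (7.50 ± 0.502 and 5.19 ± 0.176 FPKM).

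The comparison of AZ1366 with vehicle asks what tankyrase inhibition does on its own; tankyrases mark AXIN and angiomotin proteins for degradation and thereby act on Wnt and YAP signalling. Targets of YAP and TEAD fell in all 22 tested cases, with a median log2 change of -0.70. YAP targets had camera adjusted p = 4.53e-09, and 0.556 with an estimated correlation. CTGF, a canonical YAP target, went from 19.6 ± 0.110 to 9.17 ± 0.102 FPKM (chromosome 6, 132269317 to 132272518; log2 -1.02 ± 0.045, SE, n = 4; adjusted p = 2.22e-10), ANKRD1 from 13.6 ± 0.114 to 4.87 ± 0.686 (chromosome 10, 92671857 to 92681032; -1.32 ± 0.075), the receptor kinase gene AXL from 148 ± 8.65 to 59.0 ± 7.07 (chromosome 19, 41725108 to 41767671; -1.32 ± 0.070) and F3 from 228 ± 11.9 to 105 ± 8.91 (chromosome 1, 94994732 to 95007413; -1.11 ± 0.061). The largest fall was that of ADAMTS1, -2.13 ± 0.10 (adjusted p = 3.05e-10; chromosome 21, 28208606 to 28217728), followed by CENPE (-1.69 ± 0.31), ANKRD1, AXL, TCOF1 (-1.23 ± 0.15) and GOLGA4 (-1.22 ± 0.23). The largest rises were those of the chemokine gene IL8, from 4.25 ± 1.24 to 13.5 ± 2.58 FPKM (1.48 ± 0.14, adjusted p = 7.88e-07; chromosome 4, 74606223 to 74609433), C4orf48 (1.36 ± 0.17), the cornified envelope genes SPRR1A (1.33 ± 0.094) and SPRR1B (1.18 ± 0.13), LOC284801 (1.26 ± 0.20) and FXYD3 (1.14 ± 0.094).

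Of the 21 listed feedback targets of Wnt signalling, 9 reached the abundance filter. AXIN2, a widely used target, stood at 0.0746 ± 0.0285 FPKM with vehicle and 0.0202 ± 0.00782 with AZ1366 (chromosome 17, 63524683 to 63557740), a ratio of 0.270 with exact permutation p = 0.0286, the smallest that 70 assignments allow, and 0.143 after Benjamini-Hochberg adjustment over the 10 tests made of AXIN2 and NKD1. NKD1 stood at 0.0104 and 0.0135 FPKM. Of the 9 feedback targets tested, 4 fell and 0 rose, and the list did not pass (median -0.17, camera adjusted p = 0.144); after length and GC correction 3 rose and 3 fell. Wnt ligands, receptors and destruction complex genes gave 1 rise and 17 falls among 28 (camera adjusted p = 0.104), with 9 rising and 9 falling after that correction. The drug's own targets TNKS and TNKS2 did not pass, at 0.03 ± 0.055 and -0.04 ± 0.073 (adjusted p = 0.622 and 0.647), although both rose after length and GC correction (adjusted p = 0.00131 and 0.00775, TNKS2 by 0.12), TNKS rose after quantile normalization and median-ratio scaling, and TNKS2 fell without AZ1366 1 (adjusted p = 0.0424) and without CTRL 1 and AZ1366 1 together (0.0392).

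Ribosome biogenesis, cell cycle, receptor kinase, mesenchymal and fatty acid genes were lower on balance. Ribosome biogenesis genes fell in 20 of 23 cases (median -0.60), with DKC1 at -0.72 ± 0.063. For ribosome biogenesis, camera gave adjusted p = 5.46e-07, and 0.556 with an estimated correlation. G1/S and DNA replication genes fell in 22 of 36 cases and none rose (median -0.25), with MCM2 at -0.54 ± 0.074; after quantile normalization 3 rose and 20 fell (median -0.18), and after length and GC correction 0 rose and 16 fell. G1/S genes had camera adjusted p = 0.00783, and 0.73 with an estimated correlation, and the median was -0.09 after length and GC correction. G2/M genes gave 3 rises and 25 falls among 36, 3 and 26 adjusted over the list alone (median -0.38), with CDC20 at -0.61 ± 0.075. For G2/M genes, camera gave adjusted p = 0.00147, and 0.717 with an estimated correlation. Other receptor tyrosine kinases and ligands gave 1 rise and 9 falls among 11 (median -0.57), including GAS6 (-1.12 ± 0.14) and NRG1 (-0.97 ± 0.070). Other receptor kinases had camera adjusted p = 0.00453, and 0.717 with an estimated correlation, and the median was -0.29 after length and GC correction. Mesenchymal genes gave 1 rise and 14 falls among 22 (median -0.31), with THBS1 at -0.81 ± 0.10. For mesenchymal genes, camera gave adjusted p = 0.0269, and 0.73 with an estimated correlation. Fatty acid synthesis genes fell in 10 of 13 cases (median -0.32), with FASN at -0.91 ± 0.12. Fatty acid synthesis had camera adjusted p = 0.0469, but 0.73 with an estimated correlation, 0.0649 after quantile normalization, 0.267 after length and GC correction, 0.0586 without CTRL 1 and 0.0614 without AZ1366 3. The median was -0.06 after length and GC correction (2 rose, 5 fell). EGFR went from 77.7 ± 4.39 to 41.3 ± 8.92 FPKM (-0.92 ± 0.11), CCND1 changed by -0.72 ± 0.088 and MYC by -0.74 ± 0.081, whereas DUSP6 did not pass (-0.05 ± 0.080, adjusted p = 0.639) and rose by 0.13 after length and GC correction.

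Interferon-stimulated genes rose in 16 of 29 cases and 1 fell (median 0.25), with OAS1 at 0.78 ± 0.12 and IRF9 at 0.73 ± 0.10. For interferon-stimulated genes, camera gave adjusted p = 3.26e-05, and 0.717 with an estimated correlation. Among the vehicle libraries CTRL 4 stood apart on this list, with a mean log2 value of 3.63 against 3.29 to 3.32, and without it the median was 0.33 (adjusted p = 3.6e-08). Antigen presentation genes gave 8 rises and 2 falls among 17 (median 0.19), with B2M at 0.62 ± 0.087. Antigen presentation had camera adjusted p = 0.00783, but 0.556 with an estimated correlation, 0.103 after quantile normalization and 0.056 after length and GC correction. FOXO and PI3K feedback targets gave 10 rises and 3 falls among 22, 11 and 3 adjusted over the list alone (median 0.21), with HBP1 at 0.62 ± 0.049. For FOXO targets, camera gave adjusted p = 0.00147, and 0.717 with an estimated correlation, and the median was 0.33 after quantile normalization, 0.34 after length and GC correction and 0.12 without CTRL 1 and AZ1366 1. Mucin and airway secretory genes gave 6 rises and 1 fall among 7 (median 0.28), with AGR2 at 0.82 ± 0.064. Mucin and secretory genes had camera adjusted p = 0.00214, but 0.235 with an estimated correlation, 0.056 after length and GC correction. Pro-apoptotic BCL2 family genes gave 5 rises and 1 fall among 10 (median 0.10), led by BMF, which went to 14.2 ± 1.49 FPKM (1.11 ± 0.072), and BIK (0.66 ± 0.082); BCL2L11 changed by 0.17 ± 0.062 (adjusted p = 0.0247), a call that was lost in 4 other settings, among them without CTRL 3 (0.103), AZ1366 1 (0.0517) or AZ1366 4 (0.0607). For pro-apoptotic genes, camera gave adjusted p = 0.0171, but 0.556 with an estimated correlation, 0.095 after length and GC correction. The median was 0.21 after quantile normalization and 0.19 after length and GC correction (6 rose, 3 fell). Cytosolic ribosomal protein genes gave 15 rises and 0 falls among 31 as deposited (median 0.14). Ribosomal proteins had camera adjusted p = 5.01e-05, but 0.717 with an estimated correlation, 0.694 after quantile normalization and 0.563 after length and GC correction. The median was -0.01 after quantile normalization (10 rose, 7 fell) and 0.05 after length and GC correction (9 rose, 4 fell). Unless given, the counts adjusted over the list alone were the same in the 13 lists called here.

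In all, 6801 of 11647 loci passed (limma), 2168 higher and 4633 lower, and 48 changed by at least 1, 17 up and 31 down. The median of all tested loci was -0.10, and 0.00 after median-ratio scaling; relative to that shift 50% of the called loci rose, against 31.9% as deposited, and the median of the YAP targets was -0.64 after quantile normalization. The change of a locus went with its transcript length across loci (Spearman rho -0.388 over 11311 loci, which are not independent replicates), and the log2 deviation of a library from the mean of all libraries changed by 0.105 ± 0.0204 per doubling of length with vehicle against -0.0146 ± 0.0576 with AZ1366 (SD, n = 4; exact permutation p = 0.0286, the smallest possible). Camera called 13 of 33 lists, and 0 with an estimated correlation, with 1 at an unadjusted p under 0.05, while fry called 22. Without CTRL 1 and AZ1366 1, 7463 loci passed and 26.9% of them rose.

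**Figure D3:**
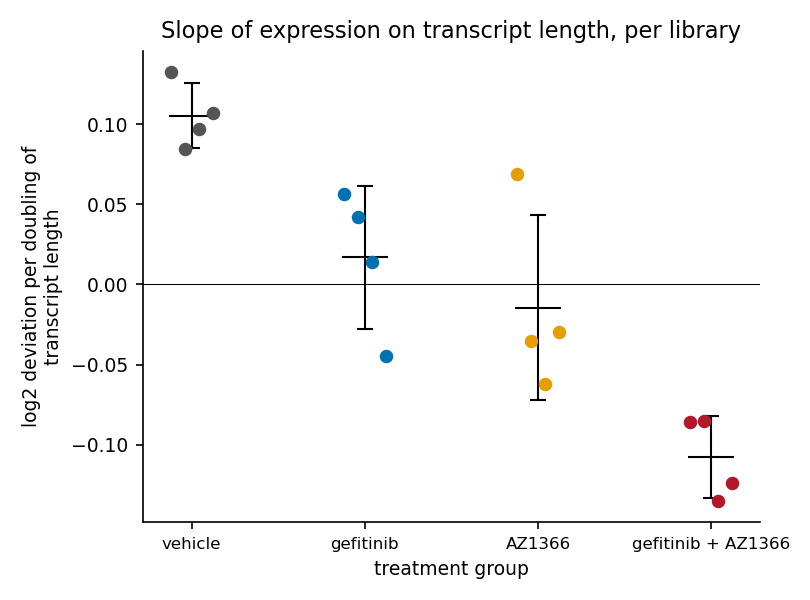
Slope of each library's log2 deviation from the mean of all libraries on transcript length, per doubling of length, for 4 libraries per treatment (points) with the group mean and SD (bars). The mean slope was 0.105 with vehicle, 0.0169 with gefitinib, -0.0146 with AZ1366 and -0.108 with both.

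The comparison of the combination with vehicle gives the state of the cells under both compounds. CXCL11 rose most in log2(FPKM + 1), from 0.605 ± 0.189 to 25.8 ± 1.05 FPKM (4.07 ± 0.089, SE, n = 4, adjusted p = 3.33e-16). CXCL10, at the same listed interval, rose from 0.149 ± 0.123 to 7.93 ± 1.03 (chromosome 4, 76932333 to 77033955). VTCN1 (3.27 ± 0.060), MMP7 (3.22 ± 0.078), C8orf4 (3.16 ± 0.082) and SPINK1 (3.13 ± 0.079) rose as well. FOSL1 (-3.13 ± 0.10), ADAMTS1 (-2.92 ± 0.10), CENPE (-2.89 ± 0.31), PHLDA1 (-2.87 ± 0.093), G0S2 (-2.83 ± 0.089) and TCOF1 (-2.63 ± 0.15) had the largest falls. BMF reached 35.3 ± 2.18 FPKM (2.37 ± 0.072), the highest of the 4 groups, and EGFR 20.8 ± 2.45 (-1.86 ± 0.11), the lowest.

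All 36 tested G1/S and DNA replication genes fell (median -1.16), with CDC6 at -2.07 ± 0.070 (chromosome 17, 38444146 to 38459413), MCM10 at -2.20 ± 0.079 and the ribonucleotide reductase gene RRM2 at -1.34 ± 0.048. For G1/S genes, camera gave adjusted p = 2.78e-11, and 0.276 with an estimated correlation. All 36 G2/M genes fell (median -1.33), with MKI67 at 4.87 ± 0.516 FPKM (chromosome 10, 129894925 to 129924468) and KIF2C at -1.46 ± 0.054. G2/M genes had camera adjusted p = 4.4e-10, and 0.305 with an estimated correlation. Ribosome biogenesis fell in 22 of 23 cases (median -1.4) and ERK output in 21 of 26, with 2 rising (median -1.39). Ribosome biogenesis had camera adjusted p = 6.21e-08, and 0.311 with an estimated correlation. ERK output had camera adjusted p = 2.82e-06, and 0.311 with an estimated correlation. YAP targets gave 1 rise and 15 falls among 22 (median -0.55), with F3 at -2.07 ± 0.061, AXL at -1.77 ± 0.070 and NT5E at -2.54 ± 0.11; CTGF stood at -0.03 ± 0.045 and did not pass (adjusted p = 0.489), and rose by 0.17 after quantile normalization and by 0.14 after median-ratio scaling. For YAP targets, camera gave adjusted p = 0.00912, and 0.685 with an estimated correlation. Fatty acid synthesis genes gave 1 rise and 11 falls among 13 (median -0.89) and cholesterol synthesis genes 1 rise and 19 falls among 24 (median -0.60), with FASN at -1.85 ± 0.12. Fatty acid synthesis had camera adjusted p = 0.00936, and 0.641 with an estimated correlation, and the median was -0.50 after length and GC correction. Cholesterol synthesis had camera adjusted p = 0.0059, and 0.563 with an estimated correlation. Glycolysis genes fell in 16 of 21 cases (median -0.25). Glycolysis had camera adjusted p = 0.0129, and 0.563 with an estimated correlation, and the median was -0.48 after quantile normalization (2 rose, 18 fell).

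Interferon-stimulated genes rose in 28 of 29 cases (median 1.23), with IFI27 at 65.0 ± 5.69 FPKM (chromosome 14, 94577079 to 94583033). For interferon-stimulated genes, camera gave adjusted p = 5.83e-13, and 0.305 with an estimated correlation. Antigen presentation genes gave 13 rises and 1 fall among 17, 14 and 1 adjusted over the list alone (median 0.89). Antigen presentation had camera adjusted p = 8e-06, and 0.276 with an estimated correlation. Lysosome genes gave 17 rises and 5 falls among 25 (median 0.36), with GABARAPL1 at 1.92 ± 0.053, and NRF2 targets 14 rises and 4 falls among 18 (median 0.34), with AKR1C3 at 1.5 ± 0.066. Lysosome genes had camera adjusted p = 0.000982, and 0.361 with an estimated correlation. NRF2 targets had camera adjusted p = 0.0027, and 0.311 with an estimated correlation. Pro-apoptotic genes gave 6 rises and 2 falls among 10 (median 0.36; BIK 1.21 ± 0.082, BBC3 1.21 ± 0.10, BCL2L11 0.69 ± 0.062), mucin and secretory genes 5 rises and 1 fall among 7 (median 0.75; SLPI 1.41 ± 0.052, SPDEF -1.34 ± 0.077) and FOXO targets 10 rises and 5 falls among 22 (median 0.06), each with camera adjusted p = 0.0129. With an estimated correlation these 3 had adjusted p = 0.311, 0.276 and 0.685, after length and GC correction the first 2 had 0.112 and 0.14, and mucins had 0.0667 after quantile normalization. The FOXO median was 0.21 after quantile normalization and 0.32 after length and GC correction. Ribosomal protein genes gave 25 rises and 0 falls among 31 as deposited (median 0.37). For ribosomal proteins, camera gave adjusted p = 1.62e-05, but 0.526 with an estimated correlation, 0.284 after quantile normalization and 0.159 after length and GC correction. The median was 0.14 after quantile normalization (17 rose, 7 fell) and 0.17 after length and GC correction (16 rose, 4 fell). The counts adjusted over the list alone were the same in the other 15 lists called.

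This comparison had the most calls of the 7: 9241 of 11647 loci passed (limma), 3488 higher and 5753 lower, and 1320 changed by at least 1, 459 up and 861 down. The median of all loci was -0.15. With median-ratio scaling, which takes out such a common shift, 50.1% of called loci rose against 37.7% as deposited. The change went with transcript length (Spearman rho -0.343). Camera called 16 of 33 lists and, with an estimated correlation, 0, with 5 at an unadjusted p under 0.05, while fry called 29.

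**Figure D4:**
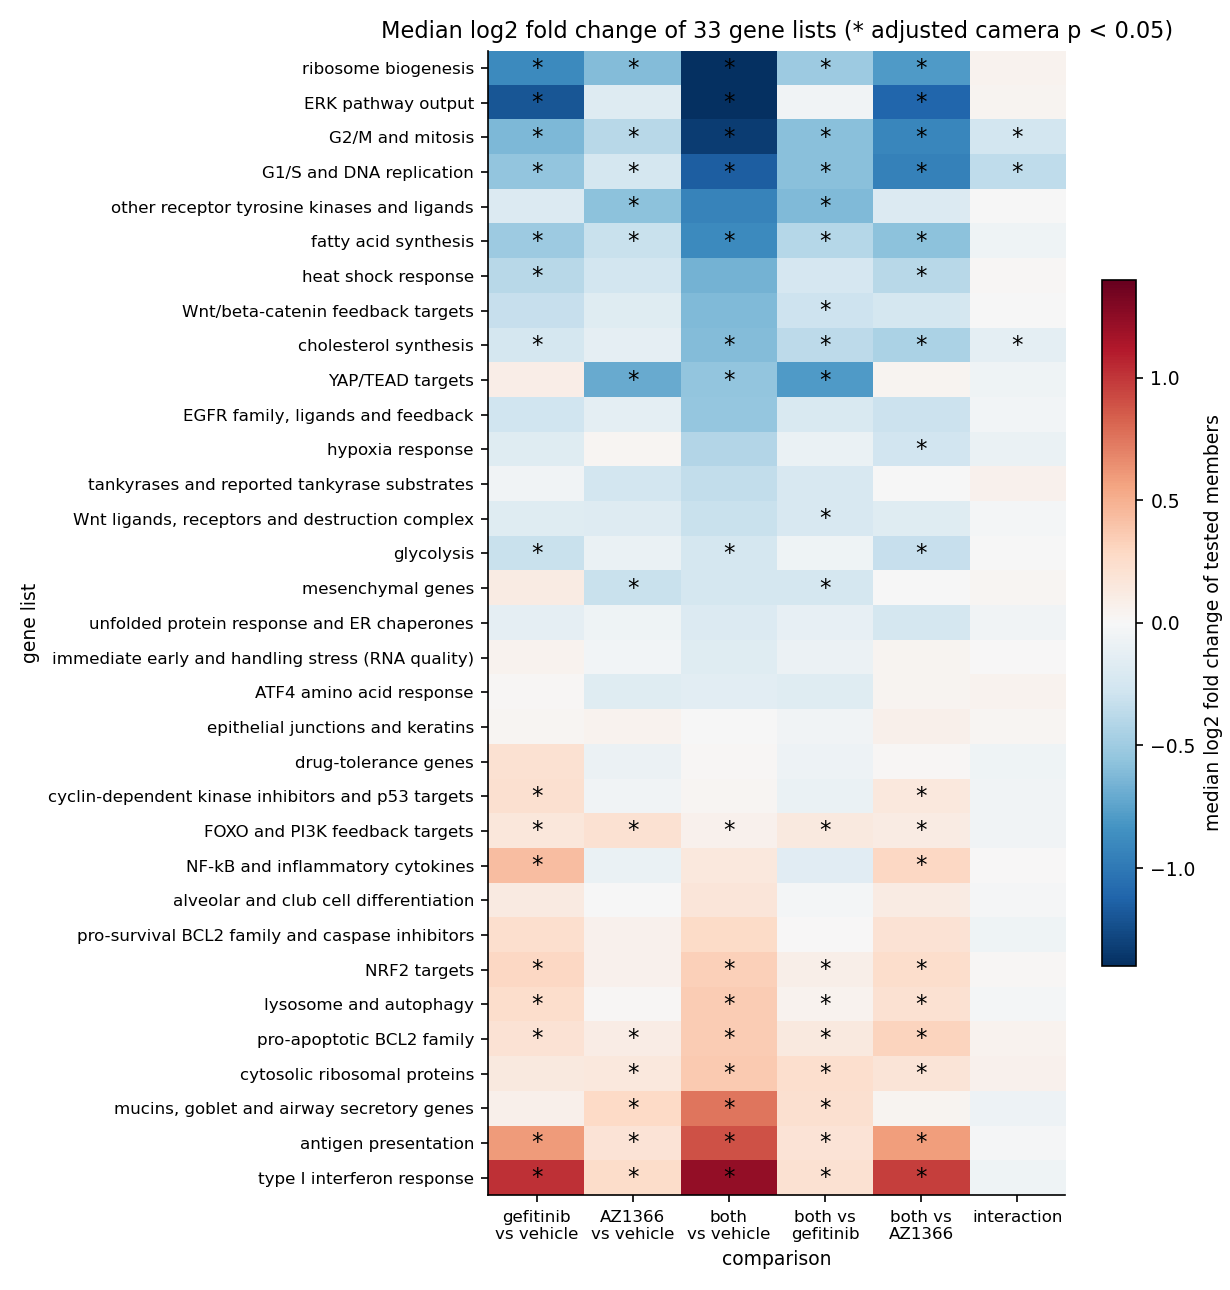
Median log2 fold change (colour) of the tested members of 33 gene lists, by list and comparison, with an asterisk where the adjusted camera p was under 0.05. YAP targets were lower with AZ1366 than without it both alone (-0.70) and on gefitinib (-0.80), and ERK output was lower with gefitinib (-1.20); the rises of ribosomal proteins became mixed after quantile normalization.

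The comparison of the combination with gefitinib asks what the tankyrase inhibitor adds once EGFR is inhibited. YAP targets fell again in all 22 cases, with a median of -0.80. YAP targets had camera adjusted p = 7.86e-11, and 0.307 with an estimated correlation. CTGF went from 45.1 ± 1.88 to 19.1 ± 0.765 FPKM (-1.20 ± 0.045, SE, n = 4; adjusted p = 1.48e-11), ANKRD1 from 21.9 ± 1.64 to 9.03 ± 0.607 (-1.19 ± 0.075) and F3 from 128 ± 7.15 to 53.5 ± 1.57 (-1.25 ± 0.061). All 36 G1/S and DNA replication genes fell further (median -0.59), with CDC6 from 16.7 ± 0.448 to 7.50 ± 0.502 FPKM (-1.06 ± 0.070), MCM10 at -1.05 ± 0.079, MCM6 at -0.79 ± 0.057 and RRM2 at -0.70 ± 0.048. For G1/S genes, camera gave adjusted p = 5.14e-16, and 0.13 with an estimated correlation. G2/M genes fell in 35 of 36 cases, all 36 adjusted over the list alone (median -0.59), with ANLN at -1.19 ± 0.10 and CDCA8 at -0.73 ± 0.049. G2/M genes had camera adjusted p = 3.13e-13, and 0.214 with an estimated correlation.

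Wnt feedback targets fell in 7 of 9 cases (median -0.29). For Wnt feedback targets, camera gave adjusted p = 0.016, and 0.527 with an estimated correlation, and the median was -0.13 after length and GC correction (1 rose, 4 fell). The secreted Wnt antagonist gene DKK1 went from 59.9 ± 3.21 to 34.2 ± 2.07 FPKM (chromosome 10, 54074041 to 54077417; -0.79 ± 0.064, adjusted p = 1.2e-07), LGR5 changed by -0.44 ± 0.059, BMP4 by -0.39 ± 0.068 and ZNRF3 by -0.29 ± 0.070, the last of which did not pass after length and GC correction (adjusted p = 0.491). AXIN2 stood at 0.0520 ± 0.00351 and 0.0255 ± 0.0138 FPKM, a ratio of 0.491 (exact permutation p = 0.0286, adjusted 0.143). Wnt ligands, receptors and destruction complex genes gave 1 rise and 18 falls among 28, 1 and 21 adjusted over the list alone (median -0.23); WLS, needed for Wnt secretion, rose by 0.38 ± 0.044 and FZD4 changed by -0.35 ± 0.053, without a call after that correction (0.139). Wnt ligands and receptors had camera adjusted p = 0.0353, but 0.818 with an estimated correlation, 0.465 after length and GC correction, 0.0518 without GEF 1 and 0.0599 without combination 3. The median was -0.13 after quantile normalization (4 rose, 12 fell) and -0.02 after length and GC correction (6 rose, 8 fell). Other receptor kinases and ligands gave 1 rise and 10 falls among 11 (median -0.61), including AXL (-1.10 ± 0.070), NRG1 (-1.03 ± 0.070) and MET (-0.58 ± 0.065), cholesterol synthesis 1 rise and 18 falls among 24, 1 and 19 adjusted over the list alone (median -0.37), and FOXO targets 8 rises and 3 falls among 22, 8 and 2 adjusted over the list alone (median 0.14). Each of these 3 lists had camera adjusted p = 0.00085, and adjusted p = 0.527 with an estimated correlation; after length and GC correction the medians of the last 2 were -0.23 and 0.27. Ribosome biogenesis genes fell in 20 of 23 cases (median -0.51), fatty acid synthesis in 10 of 13 (median -0.40) and mesenchymal genes in 12 of 22 (median -0.25), with THBS1 at -1.08 ± 0.10. Ribosome biogenesis had camera adjusted p = 2.9e-07, and 0.307 with an estimated correlation. Fatty acid synthesis had camera adjusted p = 0.00317, and 0.542 with an estimated correlation, and the median was -0.25 after length and GC correction. Mesenchymal genes had camera adjusted p = 0.0317, and 0.788 with an estimated correlation, and the median was -0.15 after length and GC correction (2 rose, 7 fell).

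CXCL11 (1.15 ± 0.089), C4orf48 (1.06 ± 0.17), LY96 (1.04 ± 0.12), CXCL10 (0.99 ± 0.091), C8orf4 (0.97 ± 0.082) and SLC2A12 (0.94 ± 0.056) had the largest rises, and ADAMTS1 (-1.46 ± 0.10), CENPE (-1.39 ± 0.31), KTN1 (-1.37 ± 0.26), WWC1 (-1.35 ± 0.11), F3 and CENPF (-1.24 ± 0.24) the largest falls. Interferon-stimulated genes gave 11 rises and 1 fall among 29 (median 0.21), antigen presentation 8 rises and 1 fall among 17 (median 0.19) and mucin and secretory genes 4 rises and 0 falls among 7 (median 0.23). Interferon-stimulated genes had camera adjusted p = 1.52e-05, and 0.527 with an estimated correlation. Antigen presentation had camera adjusted p = 0.000441, and 0.249 with an estimated correlation, and the median was 0.12 after quantile normalization. Mucin and secretory genes had camera adjusted p = 0.000264, and 0.0963 with an estimated correlation. Pro-apoptotic genes rose in 4 of 10 cases (median 0.13), with BMF at 0.47 ± 0.072, BIK at 0.51 ± 0.082 and BCL2L11 at 0.28 ± 0.062. For pro-apoptotic genes, camera gave adjusted p = 0.00347, and 0.307 with an estimated correlation, and the median was 0.23 after quantile normalization (8 rose, 0 fell). NRF2 targets gave 5 rises and 4 falls among 18, 7 and 4 adjusted over the list alone (median 0.08), and lysosome genes 7 rises and 4 falls among 25 (median 0.05). NRF2 targets had camera adjusted p = 0.00545, but 0.386 with an estimated correlation and 0.217 after quantile normalization. The median was 0.05 after quantile normalization (4 rose, 2 fell). Lysosome genes had camera adjusted p = 0.0176, but 0.527 with an estimated correlation, 0.189 by fry and 0.086 after quantile normalization. The median was 0.12 after quantile normalization (10 rose, 2 fell), 0.12 after length and GC correction (12 rose, 2 fell) and 0.03 without combination 2. Ribosomal protein genes gave 24 rises and 0 falls among 31 as deposited, 25 and 0 adjusted over the list alone (median 0.23). Ribosomal proteins had camera adjusted p = 8.07e-11, but 0.307 with an estimated correlation and 0.158 after quantile normalization. The median was 0.05 after quantile normalization (9 rose, 2 fell) and 0.14 after length and GC correction (14 rose, 0 fell). ERK output was not called (median -0.05, camera adjusted p = 0.625), and DUSP6 stood at 0.10 ± 0.080 (adjusted p = 0.294) and rose after quantile normalization, median-ratio scaling and length and GC correction (0.00158, 0.0073 and 0.000196). EGFR fell from 38.1 ± 4.06 to 20.8 ± 2.45 FPKM (-0.84 ± 0.11).

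In total 6118 of 11647 loci passed (limma), 1780 higher and 4338 lower, and 43 changed by at least 1, 4 up and 39 down. The median of all loci was -0.10, and 48.8% of called loci rose after median-ratio scaling against 29.1% as deposited. The change went with transcript length (Spearman rho -0.470 over 11311 loci), and 77.5% of called loci rose in the shortest of 5 length classes against 6.37% in the longest. Camera called 18 of 33 lists and, with an estimated correlation, 0, with 5 at an unadjusted p under 0.05, while fry called 24. The counts adjusted over the list alone were the same in the 12 called lists for which no other count is given.

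The comparison of the combination with AZ1366 asks what gefitinib adds to tankyrase inhibition. DUSP6 fell from 22.8 ± 2.63 to 2.99 ± 0.403 FPKM (-2.58 ± 0.080, SE, n = 4; adjusted p = 8.98e-14), and PHLDA1 (-2.38 ± 0.093), FOSL1 (-2.03 ± 0.10), ETV1 (-1.99 ± 0.062), NT5E (-1.93 ± 0.11) and G0S2 (-1.88 ± 0.089) fell with it. CXCL11 (3.08 ± 0.089), CXCL10 (2.85 ± 0.091), VTCN1 (2.67 ± 0.060), MMP7 (2.37 ± 0.078), NUPR1 (2.26 ± 0.088) and OAS2 (2.19 ± 0.17) rose most. ERK output fell in 24 of 26 cases (median -1.11), and all 36 G1/S genes (median -0.95) and all 36 G2/M genes fell (median -0.92). ERK output had camera adjusted p = 5.15e-12, and 0.142 with an estimated correlation. G1/S genes had camera adjusted p = 2.44e-17, and 0.129 with an estimated correlation. G2/M genes had camera adjusted p = 1.29e-14, and 0.142 with an estimated correlation. Interferon-stimulated genes rose in 27 of 29 cases (median 0.97). Interferon-stimulated genes had camera adjusted p = 1.29e-14, and 0.231 with an estimated correlation.

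Ribosome biogenesis fell in 22 of 23 cases (median -0.79), and antigen presentation gave 13 rises and 1 fall among 17 (median 0.58). Ribosome biogenesis had camera adjusted p = 1.19e-09, and 0.231 with an estimated correlation. Antigen presentation had camera adjusted p = 2.8e-06, and 0.129 with an estimated correlation. Cholesterol synthesis gave 1 rise and 19 falls among 24 (median -0.44). For cholesterol synthesis, camera gave adjusted p = 0.000224, and 0.386 with an estimated correlation. Glycolysis genes fell in 17 of 21 cases (camera adjusted p = 0.000306), lysosome genes gave 13 rises and 2 falls among 25, 15 and 2 adjusted over the list alone (camera adjusted p = 0.000485), NRF2 targets 11 rises and 1 fall among 18 (camera adjusted p = 0.0035) and pro-apoptotic genes 6 rises and 1 fall among 10 (camera adjusted p = 0.0201); each of these 4 had adjusted p = 0.322 with an estimated correlation, and pro-apoptotic genes 0.0922 after length and GC correction. Hypoxia response genes, called with gefitinib alone only in some settings, gave 3 rises and 12 falls among 19 (median -0.27, camera adjusted p = 0.0169, but 0.641 with an estimated correlation and 0.0571 after length and GC correction), with CA9 at -1.19 ± 0.078, NDRG1 at -1.31 ± 0.067 and STC1 at -1.29 ± 0.064; the difference between these effects was not called for this list (camera adjusted p = 0.572). Fatty acid synthesis gave 1 rise and 11 falls among 13 (camera adjusted p = 0.00467), NF-kB genes 8 rises and 3 falls among 14 (camera adjusted p = 0.0352), heat shock genes 1 rise and 9 falls among 15 (camera adjusted p = 0.0368) and kinase inhibitors of the cell cycle and p53 targets 10 rises and 4 falls among 21 (camera adjusted p = 0.0383), with CDKN1C at 0.95 ± 0.067. Each of these 4 had adjusted p = 0.641 with an estimated correlation, and the p53 list had 0.101 after length and GC correction and a median of 0.08 without AZ1366 2 against 0.14. Ribosomal protein genes gave 15 rises and 2 falls among 31 (camera adjusted p = 0.00467), but adjusted p = 0.641 with an estimated correlation, 0.284 after quantile normalization, 0.139 after length and GC correction and 0.0551 without AZ1366 1. FOXO targets gave 10 rises and 6 falls among 22. FOXO targets had camera adjusted p = 0.0368, and 0.668 with an estimated correlation, and the median was 0.26 after length and GC correction, 0.23 without AZ1366 1 and 0.06 without AZ1366 2. The counts adjusted over the list alone were the same in the other 17 lists called. Of 11647 loci 7294 passed (limma), 3135 higher and 4159 lower, and 391 changed by at least 1, 199 up and 192 down. Changes went with transcript length (Spearman rho -0.234). Camera called 18 of 33 lists, 0 with an estimated correlation (6 at an unadjusted p under 0.05), and fry 25.

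The interaction asks whether either compound acts differently in the presence of the other; a negative value means that the combination lay below the sum of the single log2 changes. Genes of G1/S and DNA replication were lower than additive: 19 of 36 passed below 0 and none above, 27 adjusted over the list alone, with a median of -0.35 (fry adjusted p = 0.000432). For G1/S genes, camera gave adjusted p = 4.03e-27, and 0.0442 with an estimated correlation. The cyclin gene CCNE2 stood at 12 ± 1.25, 8.75 ± 0.232, 13.1 ± 0.863 and 5.19 ± 0.176 FPKM with vehicle, gefitinib, AZ1366 and both (interaction -0.77 ± 0.092, SE, n = 4; adjusted p = 0.00115), and CDC6 at 34.6 ± 0.990, 16.7 ± 0.448, 25.6 ± 3.32 and 7.50 ± 0.502 (-0.63 ± 0.10, adjusted p = 0.00445); RRM2 (-0.49 ± 0.068) and MCM6 (-0.57 ± 0.081) were lower than additive too. G2/M genes were below additive in 7 of 36 cases, 16 adjusted over the list alone (median -0.26), with UBE2C at -0.48 ± 0.077, and cholesterol synthesis in 4 of 24, 8 adjusted over the list alone (median -0.13), with HMGCS1 at -0.46 ± 0.071. G2/M genes had camera adjusted p = 6.25e-14, and 0.281 with an estimated correlation. Cholesterol synthesis had camera adjusted p = 8.75e-05, but 1 with an estimated correlation and 0.231 by fry. The median was -0.05 without AZ1366 1 and -0.09 without combination 3. YAP targets and interferon-stimulated genes showed no departure that passed, with 0 members called by limma in each and medians of -0.06 and -0.06 (camera adjusted p = 0.96 and 0.827), except that the interferon list passed without CTRL 4 (median -0.14, adjusted p = 0.037).

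CXCL10 lay above additive, at 0.149 ± 0.123, 3.48 ± 0.417, 0.233 ± 0.0847 and 7.93 ± 1.03 FPKM in the same order (0.89 ± 0.13, adjusted p = 0.00231), as did ADAMTS1 (0.67 ± 0.14), COL8A1 (0.65 ± 0.13), GLI4 (0.59 ± 0.12), DDIT4L (0.58 ± 0.094) and MARCHF4 (0.56 ± 0.12). FAM111B (-0.92 ± 0.17, adjusted p = 0.00938), CCNE2, HMGB2 (-0.72 ± 0.17), CCL2 (-0.66 ± 0.082, adjusted p = 0.00115), BMF (-0.64 ± 0.10) and CDC6 lay furthest below. BMF and CCL2 rose with each compound and reached their highest level with both, by less than the sum of the single changes. With a pseudocount of 0.1 CXCL10 (adjusted p = 0.397), ADAMTS1 (0.774), COL8A1 (0.0834) and MARCHF4 (0.365) did not pass. Calls also ended without single libraries, with the highest adjusted p at 0.102 for HMGB2 (without CTRL 4), 0.0595 for MARCHF4 (AZ1366 4), 0.0521 for GLI4 (CTRL 4), 0.0507 for ADAMTS1 (AZ1366 4) and just above 0.05 for COL8A1 (AZ1366 4). In all 212 of 11647 loci passed (limma, Benjamini-Hochberg), 38 above and 174 below additive, with a median absolute value of 0.41; by limma 0 of them reached 1 on the log2 scale, and 1672 loci had an unadjusted p under 0.05. The balance was 256 above and 258 below without AZ1366 1, 274 and 346 after quantile normalization, 125 and 294 after median-ratio scaling, 250 and 386 after length and GC correction and 112 and 180 without CTRL 1 and AZ1366 1. Of the 174, 41 were lowered by both compounds and 42 raised by both. The count was 99 without CTRL 4 and 514 without AZ1366 1, and between 103 and 139 without CTRL 1, GEF 1, GEF 2, GEF 3, AZ1366 4 or any of the combination libraries; the G1/S count was 9 without CTRL 4 and between 10 and 12 without CTRL 1, GEF 1, GEF 2, AZ1366 4 or combination replicate 1, 3 or 4.

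Across 11647 loci, which are not independent replicates, the AZ1366 effect without gefitinib correlated with that on gefitinib at Pearson r = 0.840 (jackknife SE 0.0433) and Spearman rho = 0.844, with a slope of 0.742, and 4727 of the 4754 loci called in both had the same sign, against 2057 from the marginal counts alone. The gefitinib effect without AZ1366 correlated with that on AZ1366 at r = 0.925 (jackknife SE 0.0295) and rho = 0.914, and 6096 of 6108 loci called in both had the same sign, against 2402. The effects in each pair share no library.

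**Figure D5:**
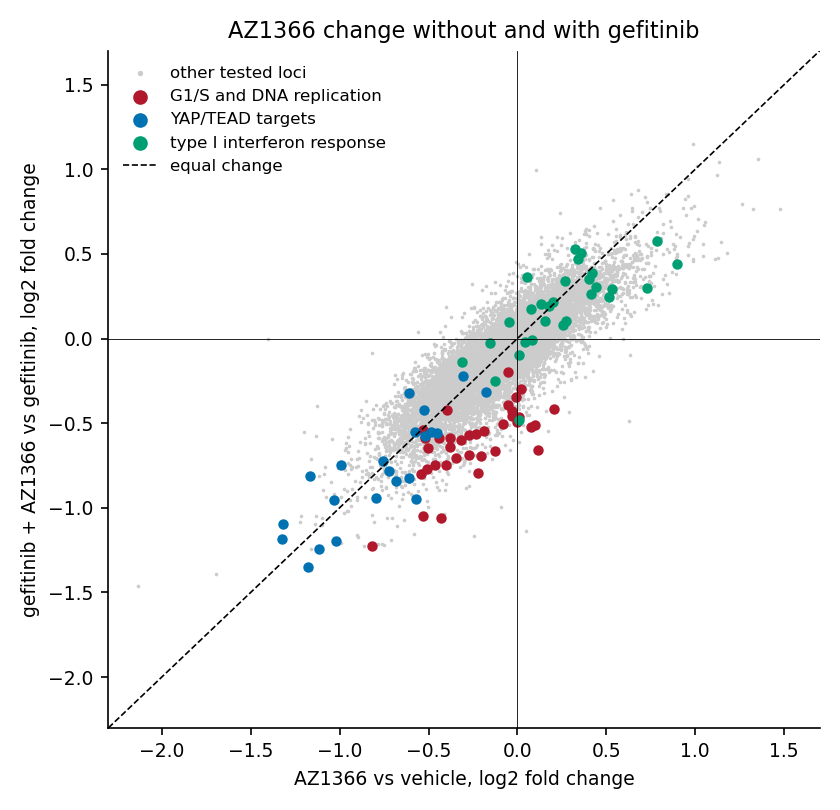
Log2 fold change of AZ1366 without gefitinib (horizontal axis) against that on gefitinib (vertical axis) for 11646 tested loci, with 1 locus outside the axes; colours mark 3 gene lists and the dashed line equal change. YAP targets lie below 0 on both axes, and most G1/S genes lie below the dashed line (median -0.25 without and -0.59 with gefitinib).

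The AZ1366 effect averaged over both gefitinib conditions uses all 8 libraries with the compound and all 8 without it. ADAMTS1 (-1.80 ± 0.070, SE, n = 8), CENPE (-1.54 ± 0.22), WWC1 (-1.27 ± 0.078), KTN1 (-1.27 ± 0.18), ANKRD1 (-1.25 ± 0.053) and AXL (-1.21 ± 0.049) fell most, and C4orf48 (1.21 ± 0.12), IL8 (1.12 ± 0.10), LY96 (1.09 ± 0.084), CXCL11 (1.07 ± 0.063), SPRR1A (1.05 ± 0.066) and C8orf4 (1.04 ± 0.058) rose most. All 22 YAP targets fell (median -0.76, camera adjusted p = 1.26e-08), with CTGF at -1.11 ± 0.032 (adjusted p = 1.45e-13), and so did 35 of 36 G1/S genes (median -0.44, camera adjusted p = 1.65e-08), 32 of 36 G2/M genes (median -0.52, camera adjusted p = 1.12e-07) and 21 of 23 ribosome biogenesis genes (median -0.58, camera adjusted p = 7.18e-07). Ribosomal protein genes rose in 22 of 31 cases as deposited (camera adjusted p = 1.65e-08), but in 13 with 6 falls after quantile normalization (adjusted p = 0.379, and 0.0891 after length and GC correction); these 5 lists each had adjusted p = 0.376 with an estimated correlation. The G1/S median was -0.28 after length and GC correction. Wnt feedback targets fell in 6 of 9 cases (median -0.23), with DKK1 at -0.74 ± 0.045. Wnt feedback targets had camera adjusted p = 0.0432, but 0.651 with an estimated correlation, 0.237 after length and GC correction and 0.0564 without GEF 4. The median was -0.05 after length and GC correction (2 rose, 3 fell). Interferon-stimulated genes gave 18 rises and 2 falls among 29. For interferon-stimulated genes, camera gave adjusted p = 4.24e-06, and 0.587 with an estimated correlation, and the median was 0.32 after quantile normalization (22 rose, 0 fell). The other 11 called lists ran from mucins to cholesterol synthesis, and 10 of all 18 kept their call in the 20 other settings in which lists were tested with camera's preset correlation. Mucin and secretory genes had camera adjusted p = 0.000487, and 0.123 with an estimated correlation. Cholesterol synthesis had camera adjusted p = 0.0452, but 0.703 with an estimated correlation, 0.0579 with the replicate number as a block, 0.0723 without GEF 3, 0.0669 without GEF 4, 0.0841 without AZ1366 1, 0.0647 without combination 1 and 0.0675 without CTRL 1 and AZ1366 1. The median was -0.17 after length and GC correction. Those that did not included NRF2 targets (0.579 with an estimated correlation, 0.242 after quantile normalization, 0.0626 after length and GC correction), lysosome genes (0.628 with that estimate, 0.073 after quantile normalization and 0.0514 by fry), pro-apoptotic and fatty acid genes (0.376 and 0.703 with that estimate, and 0.0654 each after length and GC correction) and Wnt ligands and receptors (0.8 with that estimate, 0.677 after that correction, 0.0513 without GEF 1, 0.0537 without AZ1366 3 and 0.0516 without combination 3). The counts adjusted over the list alone were the same in these 7 lists. In total 8126 of 11647 loci passed (limma), 2530 higher and 5596 lower, or 31.1% higher, against 49.6% after median-ratio scaling and 50.6% after length and GC correction; 32 changed by at least 1, 8 up and 24 down. Camera called 18 of 33 lists, 0 with an estimated correlation and 3 at an unadjusted p under 0.05 with that estimate, while fry called 25.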

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

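The tests of transcript length against the surplus of falls and all 3 tests of the G1/S interaction were chosen only after the result was seen; the scaling without the most abundant loci and all regroupings of libraries were fixed before.

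The screen for single libraries far from their group covered 160 sets of 4 libraries: the 28 genes whose levels are printed, chosen after their values were seen, and 12 other values. It marked 10 of them, where 5% are expected by chance; over all 197 genes of the naming rule with those of the text it marked 54 of 836. CTRL 1 had a position on the AZ1366 effect of -0.174, against 0.0417 to 0.0846 in the other vehicle libraries (slope of its difference from the other vehicle libraries on the AZ1366 effect measured with gefitinib). AZ1366 1 had a position of 0.585, against 1.03 to 1.10. The mean of the interferon list was 3.63 in CTRL 4, in log2(FPKM + 1), against 3.29 to 3.32, and CXCL11 stood at 0.884 FPKM there against 0.488 to 0.553. In GEF 4 ANKRD1 stood at 19.4 FPKM against 22.3 to 22.9, F3 at 139 against 124 to 126 and TNKS2 at 15.5 against 16.6 to 16.8. MYC stood at 2.91 FPKM in GEF 1 against 2.75 in the others, CCND1 at 209.9 in CTRL 1 against 191 to 193, and PHLDA1 at 35.1 in AZ1366 1 against 24.1 to 25.8.

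The interaction term, which tests whether the effect of AZ1366 differs with and without gefitinib, passed for 3 lists, with medians of -0.35 for G1/S and DNA replication, -0.26 for G2/M and mitosis and -0.13 for cholesterol synthesis. With an estimated correlation camera kept the first (adjusted p = 0.0442) and lost the others (0.281 and 1), and without AZ1366 1 or combination 3 the cholesterol median was -0.05 or -0.09. Ribosomal proteins (median 0.06, adjusted p = 0.0557) passed above 0 in 9 of 20 other settings (lowest adjusted p = 5.04e-05). Among the named genes it passed above 0 for CXCL10 0.89, ADAMTS1 0.67, COL8A1 0.65, GLI4 0.59, DDIT4L 0.58, MARCHF4 0.56, ANGPTL4 0.45 and SLPI 0.33. It passed below 0 for FAM111B -0.92, CCNE2 -0.77, HMGB2 -0.72, CCL2 -0.66, BMF -0.64, CDC6 -0.63, MCM6 -0.57, FXYD3 -0.57, SPRR1A -0.56, STARD4 -0.54, VTCN1 -0.52, MCM10 -0.52, MSMO1 -0.51, FBXO32 -0.51, CDK1 -0.50, RRM2 -0.49, UBE2C -0.48, BIRC3 -0.47, HMGCS1 -0.46, TTK -0.44, LGR5 -0.43, GINS2 -0.42, CDCA8 -0.37, FEN1 -0.36, YPEL3 -0.35 and AURKA -0.30. Leaving out 1 library ended some of these calls, with the highest adjusted p at 0.105 for AURKA and 0.102 for HMGB2 (both without CTRL 4), 0.0921 for SPRR1A (GEF 1), 0.0810 for FXYD3 (CTRL 4), 0.0792 for SLPI and 0.0732 for YPEL3 (AZ1366 4), 0.0618 for FEN1 (combination 3), 0.0616 for TTK (GEF 1) and 0.0595 for MARCHF4 (AZ1366 4). The others were 0.0563 for MCM10 and 0.0557 for BIRC3 (GEF 1), 0.0521 for GLI4 and 0.0508 for ANGPTL4 (CTRL 4), and 0.0507 for ADAMTS1 and just above 0.05 for COL8A1 (AZ1366 4).

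Genes of G1/S and DNA replication fell more under both compounds than the sum of the single changes, a median of -0.35. A weak response of AZ1366 1 is argued against as the cause, since the median was -0.32 without that library, and so is a trend with transcript length and GC content, since it was -0.37 after the correction. The log scale stays open: in mean FPKM relative to vehicle 25 of 36 genes had a negative interaction, with AZ1366 at a median of -16.6% of the vehicle level alone and -24.7% on gefitinib, which does not decide it. A joint action of the compounds on entry into S phase is a candidate explanation that these data could not separate from a shift in the mix of cell cycle phases.

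More loci fell than rose with AZ1366 averaged over gefitinib, with 31.1% of called loci rising. Scaling without the 100 most abundant loci left 32.5% rising, but median-ratio scaling 49.6%, so a shift in composition stays open. The surplus went with transcript length: 74.9% of called loci rose in the shortest of 5 length classes and 10.2% in the longest, a difference of 64.8 points. A length trend that varies between libraries without regard to AZ1366 is argued against by an exact permutation test of the slopes within gefitinib arms (p = 0.000408, the smallest of 4900 assignments). A change in RNA quality or in library making that went with the treatment, and a change in the cells that depends on transcript length, cannot be separated here and may each be the cause.

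Regrouping the libraries asked whether chance gives as many calls. In every pairwise comparison the real grouping alone (1 of 35) gave as many loci. Gefitinib, and the combination against vehicle, gefitinib and AZ1366, gave 7521, 9241, 6118 and 7294 against highest others of 0, 1, 0 and 0. Large differences widen the spread on regrouping and 1 of 35 is the lowest rank, so chance, in assignment or between cultures, is not excluded. AZ1366 against vehicle gave 6801. Exchanging AZ1366 1 with CTRL 2, 3 or 4 gave 5172, 4829 or 4418, which points to its place between the groups. For the averaged AZ1366 effect 1 of 100 drawn regroupings, the real one, gave 8126 loci, and the highest other gave 3168, again with AZ1366 1 moved. For the interaction this cannot tell, as the AZ1366 effect enters it or the spread. Of 100, 4 reached the real 212 and the next 41. Exchanging all gefitinib and combination labels measures the AZ1366 effect (8126), and those with 5335 and 3116 nearly do.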

How the results depend on the processing

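The length and GC correction and the joint removal of CTRL 1 and AZ1366 1 were chosen only after the results were seen; the other alternatives were fixed before the data were examined. Of the counts of loci and lists and the agreement of effects, 98 values under other settings stayed within 1.5 times the reported value (the agreement within its spread) and 19 did not; with single libraries left out 164 stayed and 12 did not. A minimum absolute log2 change of 1 left 382, 48, 1320, 43, 391, 0 and 32 loci in gefitinib, AZ1366, the combination against vehicle, against gefitinib and against AZ1366, the interaction (limma; 1672 at an unadjusted p under 0.05) and the averaged effect; the stricter criterion itself is the cause. Camera with an estimated correlation called 0 lists in each comparison except the interaction, where it called 1, with 6, 1, 5, 5, 6, 2 and 3 lists at an unadjusted p under 0.05; that tool widens the null by the correlation within a list. Fry called 22 lists for AZ1366 and 29 for the combination against vehicle; it does not compare with other genes. The interaction called 620 loci after quantile normalization, 419 after median-ratio scaling and 636 after length and GC correction, with 44.2%, 29.8% and 39.3% above additive against 17.9%; the interaction as deposited went with GC content (Spearman rho 0.487 over 11311 loci), but the cause was not tested. Without single libraries it called from 99 (without CTRL 4) to 514 (without AZ1366 1) loci and 3 to 5 lists (5 without CTRL 4); the other counts moved beyond 1.5 times were 131 (CTRL 1), 110 (GEF 1), 122 (GEF 2 and GEF 3), 103 (AZ1366 4), 124, 139, 128 and 134 (combination 1 to 4).

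Of the values of named genes 10717 kept their side of the threshold, 129 lost and 37 gained a call, and 13 reversed; all reversals went from a fitted fall to a rise with a call, and their cause was not tested. After length and GC correction they were, with adjusted p, DUSP6 0.0221 and TNKS2 0.00775 with AZ1366, TNKS 7.61e-06 with the combination against vehicle, TNKS 0.0124 and TNKS2 0.000824 against gefitinib, TNKS 0.0459 against AZ1366, and TNKS 0.000150 and TNKS2 7.61e-05 for the averaged effect. After quantile normalization they were CTGF 0.00620 with the combination against vehicle and TNKS 0.0393 and TNKS2 0.0275 for the averaged effect, and after median-ratio scaling CTGF 0.0232 and TNKS 0.0462 with the combination against vehicle. The share of rises moved by over 10 points under quantile normalization, median-ratio scaling and length and GC correction, to 48%, 50% and 48.8% for AZ1366, 48.6%, 50.1% and 49.0% for the combination against vehicle, 49.6%, 48.8% and 51.7% against gefitinib, and 49.3%, 49.6% and 50.6% for the averaged effect. Of the called loci with a length, 6741 of 7325, 4689 of 6628, 7317 of 8989, 4008 of 5949, 6466 of 7099, 172 of 206 and 5496 of 7898 kept call and sign after the correction, and 0, 94, 324, 16, 0, 0 and 338 reversed, in the order above; quantile normalization reversed 7, 2 and 2 in the combination against vehicle, against gefitinib and the averaged effect. Lists were also tested after quantile normalization and length and GC correction, with the replicate number as a block and with libraries left out; the called lists that held in all of these were 12 of 16, 8 of 13, 13 of 16, 14 of 18, 14 of 18, 3 of 3 and 10 of 18, in the order above, and 15 of 17, 17 of 20, 16 of 17, 14 of 15, 15 of 15, 28 of 30 and 14 of 15 others stayed uncalled. Calls gained with AZ1366 were NRF2 targets in 5 settings (lowest adjusted p = 0.0268) and lysosome genes in 4 (0.0137), and heat shock genes passed after quantile normalization with AZ1366 (0.0302), the combination against vehicle (0.0120) and against gefitinib (0.00820) and the averaged effect (0.0119). Without CTRL 1 and AZ1366 1 the interaction called 292 loci and the averaged effect 8582. Replicate numbers were not taken as pairs, since not every same-number pair of libraries deviated together: their correlations had a median of 0.215 (-0.091 for other numbers) and ran from -0.447 to 0.539, 16 of 24 were over 0.1, and 8 of 16 libraries resembled their own number most. A partial sharing by number stays possible, and with the number as a block 7864, 7131, 9388, 6522, 7613, 227 and 8287 loci passed. The depth is unknown, so no limit from counting can be set on loci near 0 FPKM.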

Other observations

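The test of the shared effect without proliferation genes and that after length and GC correction were fixed before their results were seen, and that with separate libraries was chosen after; the genes named in the next paragraphs were chosen after their values were seen.

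Lists without a call under gefitinib held genes that went opposite ways. YAP targets gave 9 rises and 10 falls among 22 (median 0.10, camera adjusted p = 0.677), or 12 rises and 10 falls after length and GC correction: CTGF rose by 1.16 ± 0.045 (adjusted p = 7.37e-13), TGFB2 by 1.28 ± 0.10, IGFBP3 by 1.06 ± 0.12 and GADD45A by 0.99 ± 0.19, while NT5E, F3 (-0.82 ± 0.061) and AXL (-0.67 ± 0.070) fell. Alveolar and club cell genes gave 4 rises and 4 falls among 10 (median 0.13, adjusted p = 0.243): the phosphate transporter gene SLC34A2 (1.93 ± 0.053), HOPX (1.85 ± 0.081), MUC1 (1.12 ± 0.10) and LAMP3 (0.83 ± 0.071) rose, and the 4 falls ran from -0.78 to -0.14. EGFR family genes gave 3 rises and 7 falls among 12 (median -0.28, adjusted p = 0.176): the ligand gene AREG fell by 1.55 at the first of 2 loci, whereas the receptor genes ERBB2 (0.48 ± 0.11) and ERBB3 (0.43 ± 0.077) rose. Hypoxia genes gave 4 rises and 10 falls among 19 (median -0.17, adjusted p = 0.0582), with VEGFA at -1.12 ± 0.11 and ANGPTL4 at -1.51 ± 0.066; the list passed without CTRL 2, CTRL 3 or GEF 3 (lowest adjusted p = 0.0388). Pro-survival genes gave 4 rises and 1 fall among 7 (median 0.24, adjusted p = 0.292), with BIRC3 at 1.27 ± 0.072 and BCL2L1 at -0.65 ± 0.054. Mucin and secretory genes gave 3 rises and 2 falls among 7 (median 0.07, adjusted p = 0.176), epithelial junction genes 8 rises and 6 falls among 24 (median 0.03, adjusted p = 0.338), mesenchymal genes 8 rises and 7 falls among 22 (median 0.12, adjusted p = 0.338) and drug-tolerance genes 10 rises and 8 falls among 19 (median 0.21, adjusted p = 0.338).

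The remaining lists gave, under gefitinib, 2 rises and 6 falls among 9 (median -0.33, adjusted p = 0.451) for Wnt feedback targets, with LGR5 at 0.66 ± 0.059, 7 rises and 14 falls among 28 (median -0.17, adjusted p = 0.458) for Wnt ligands, receptors and destruction complex, 4 rises and 3 falls among 20 (median -0.05, adjusted p = 0.868) for tankyrases and their substrates, 3 rises and 5 falls among 11 (median -0.19, adjusted p = 0.454) for other receptor kinases, 10 rises and 7 falls among 25 (median 0.02, adjusted p = 0.338) for the ATF4 response, 4 rises and 7 falls among 17 (median -0.13, adjusted p = 0.677) for the unfolded protein response, 4 rises and 4 falls among 11 (median 0.04, adjusted p = 0.338) for immediate early genes and 12 rises and 1 fall among 31 (median 0.13, adjusted p = 0.0847) for ribosomal proteins, which passed without CTRL 2 or GEF 1 and with the replicate number as a block (lowest adjusted p = 0.0276). Adjusted over the list alone the counts were 9 and 7 for mesenchymal, 11 and 8 for drug-tolerance, 7 and 15 for Wnt ligand and receptor, 10 and 8 for ATF4 and 10 and 1 for ribosomal protein genes, and the same for the others. Too few members passed the filter to test the histones (HIST1H1C 0.55 ± 0.087, HIST1H2BO 0.27 ± 0.075), the immune markers (CD68 0.54 ± 0.055) and the fibroblast and endothelial markers (KDR 0.90 ± 0.061, COL1A1 0.14 ± 0.061). Of these COL1A1 was not called (adjusted p = 0.0505, and 0.0338 without CTRL 1), and HIST1H2BO was not after length and GC correction (0.263). With AZ1366 the tankyrase substrate list gave 1 rise and 11 falls among 20 (camera adjusted p = 0.14), among them AMOTL2, an angiomotin family gene and YAP target (-1.03 ± 0.11, and -0.96 ± 0.11 on gefitinib), AXIN1 (-0.68 ± 0.11 and -0.48 ± 0.11) and RNF146 (0.22 ± 0.072), whose call ended without CTRL 4 (adjusted p = 0.0527) and without CTRL 1 and AZ1366 1 together (0.0763). ERK output with AZ1366 gave 4 rises and 13 falls among 26, 4 and 14 adjusted over the list alone and 10 and 8 after length and GC correction, with the receptor gene EPHA2 at -1.13 ± 0.11 and FOSL1 at -1.10 ± 0.10.

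The main effects of the compounds resembled each other across 11647 loci (Pearson r = 0.639, jackknife SE 0.0618, Spearman rho = 0.660). Both use all 16 libraries, but sharing them is argued against as the source: where each effect was measured in libraries that the other did not use, r ran from 0.470 to 0.735 over 1296 splits (median 0.630), against 0 for unrelated effects. A trend with length and GC content is argued against as the source, since r was 0.635 after the correction. Proliferation and ribosome biogenesis stay open: r was 0.598 over 6937 loci left without those lists and loci following them within groups (4710 removed). Those following them only between groups stayed. With both steps r was 0.613. A program of these cells shared by the 2 compounds, a common stress response and a technical difference that went with both treatments were not tested and stay open.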
